A study of Mus musculus with 98 samples.

How the data were processed

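Total RNA was extracted with TRIzol from mouse TBLC cultures, and libraries were made with either of 2 stranded kits and read on either of 2 instruments. Which kit or instrument served which library is not given. The 98 samples fall into 49 groups of 2 replicates: undifferentiated TBLC with the sorted EPI-T and PrE-T cells, 3 steady-state siRNA groups in diffTBLC, IP and input of the Igf2bp3 and Ythdf2 immunoprecipitations, 8 groups in each of 4 actinomycin D courses read at 0, 1, 2 and 3 h, TBLC2, and m6A immunoprecipitations of 3 states with their inputs. The m6A inputs came without a file of their own and were not analysed here.

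The gene tables hold raw counts per gene symbol that the authors deposited, whole numbers in every library used. Per the submitters' processing notes the upstream tools were FastQC 0.12.1, Trim Galore, STAR 2.7.11b, Subread and DESeq2, with genome build mm39. The peak files hold scores of peaks that the authors deposited with strand and coordinates for each m6A replicate, of which the scale is not stated and the lowest is 20. Columns named TBLC_S in 1 course were read as TBLC_PlaB-, the only arm of that table without columns of its own. Each table holds 21812 symbols. Of 21813 distinct symbols, 21144 were found in a table of gene names and 21123 in a RefSeq gene table of an older build. Counts of close paralogs such as the Zscan4 and histone genes depend on how reads shared between copies were assigned, which is not stated.

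Each table was normalized on its own (TMM) and tested in R 4.3.3 with edgeR 4.0.16 quasi-likelihood fits, after filterByExpr on the groups of the table, with Benjamini-Hochberg adjustment and a threshold of 0.05. In the actinomycin D tables, groups at 0 h were compared from a fit of all arm and time means, and slopes came from a fit of each arm against time, in log2 units per hour. No spike-in is described, so slopes are relative to the centre of all transcripts and say nothing of absolute half-lives. CPM are means over replicates ± SD, scaled on the genes left by the filter. CPM of the same group at several hours and of TBLC2 were scaled on all genes, before the filter,. The log2 changes carry the standard error of the fit. Fold bounds for genes without a count in a group use a floor of 3 counts over the group, and these bounds and intervals cover counting error only.

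A set of 22 gene lists was tested with camera in limma 3.58.1, with a preset correlation of 0.01 and, as an alternative, an estimated one, each adjusted over the lists of a comparison. List counts were also adjusted over the list alone. Sets of genes taken from one table (4-fold between PrE-T and EPI-T, 2-fold in Igf2bp3 RIP) were followed in the others, and the Igf2bp3 RIP set was also set against 10000 random lists matched on expression in the slopes. Peaks of the same strand that overlap by at least 1 base were counted as shared, and consensus peaks are those found in both replicates. Peaks could not be assigned to genes without an mm39 annotation, so tests of m6A-marked genes were not run.

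Genes were named by a rule: 12 anchors (Pdgfra, Gata6, Gata4, Sox17, Sox7, Nanog, Sox2, Pou5f1, Mettl3, Virma, Igf2bp3 and Ythdf2), the 8 largest rises and 8 largest falls past the threshold with a mean log2 CPM of at least 3 and groups that do not overlap (6 and 6 for slopes), and up to 4 members of each list with the lowest adjusted p, or any member where all counts of a list are given. Groups, comparisons, lists, this rule and the alternatives were chosen before the data were examined, except that averages over 1 to 3 h, the 1 h difference and slopes over 1 and 2 h alone were added after the values of siNC1 and siNC2 at 0 h had been seen. Also added after the data were seen were the genes 4-fold apart between PrE-T and EPI-T as sets, and the RIP sets in the slopes other than Igf2bp3 RIP in siIgf2bp3.

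Alternatives tried were DESeq2 1.42.0, RLE scaling, library totals, no filter, the replicate number as a block, fits of only the libraries compared, leaving out each library in turn and, for slopes, scaling to ribosomal protein genes, leaving out 0 h and comparing 3 h with 0 h. On simulated data with the depths and spreads of these tables, edgeR recovered 95% to 100% of changes of 1 on the log2 scale and 63% to 100% of changes of 0.5, and slope differences of 0.5 per hour in 92% to 100% and of 0.25 in 41% to 92% of cases. False calls made up 0% to 8.2%. These rates are for the simulated genes and need not hold for the real slopes. In none of 43 replicate pairs were the libraries identical. TBLC2 has no comparison group and is described in the closing section only. Some genes that the rule names are not reported here.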

Results

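RNA from mouse totipotent blastomere-like cells (TBLC), a cultured state that shares transcripts with the early cleavage embryo, was sequenced before and after the cells were moved from 2MYCP to SLM medium. In SLM part of the culture takes on a primitive endoderm (PrE) identity. The 8 h arm is labelled PlaB-, so a loss of PlaB may be part of the move and was not separated from it. Of the 98 samples, 86 had counts and 6 had m6A peak lists. Library totals ran from 20302848 to 29471283 counts in the sorted cells and undifferentiated TBLC and from 3968442 to 4750020 in the steady-state siRNA libraries. They ran from 5236928 to 12177033 in the Igf2bp3 and from 2483808 to 12666298 in the Ythdf2 immunoprecipitations (RIP), and from 11433895 to 23145666 in the 4 actinomycin D courses. Every group had n = 2, CPM are means ± SD, log2 changes are given ± standard error, and adjusted p-values come from edgeR unless another tool is named. These p-values measure only the spread between these samples, which may be technical.

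To see what separates the cells sorted after 3 days in SLM, CD140-positive cells (PrE-T) were compared with CD140-negative cells (EPI-T). Transcripts of the transcription factors that specify PrE were found almost only in PrE-T: Gata6 measured 212 ± 9.5 against 2.96 ± 0.047 CPM (log2 6.16 ± 0.10, n = 2), and Gata4 (7.50 ± 0.084), Sox17 (7.01 ± 0.12) and Sox7 (5.24 ± 0.13) rose with it. Genes for the basement membrane that PrE cells secrete were abundant, with Col4a1 at 6150 against 75.1 and Lama1 at 4850 against 84.9. The endocytic receptor gene Cubn stood at 2250 against 7.49. The pluripotency factor Nanog went the other way, at 14.8 ± 0.035 against 195 ± 15 CPM (-3.72 ± 0.081), as did Sox2 (-3.56 ± 0.087) and the Nodal co-receptor Tdgf1 (-4.11 ± 0.059). Pou5f1 was only 0.39 lower on the log2 scale, at 454 against 593 CPM. Pdgfra encodes CD140a, so its 373 ± 2.0 against 4.63 ± 1.0 CPM checks the sort and is no finding.

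**Figure D1:**
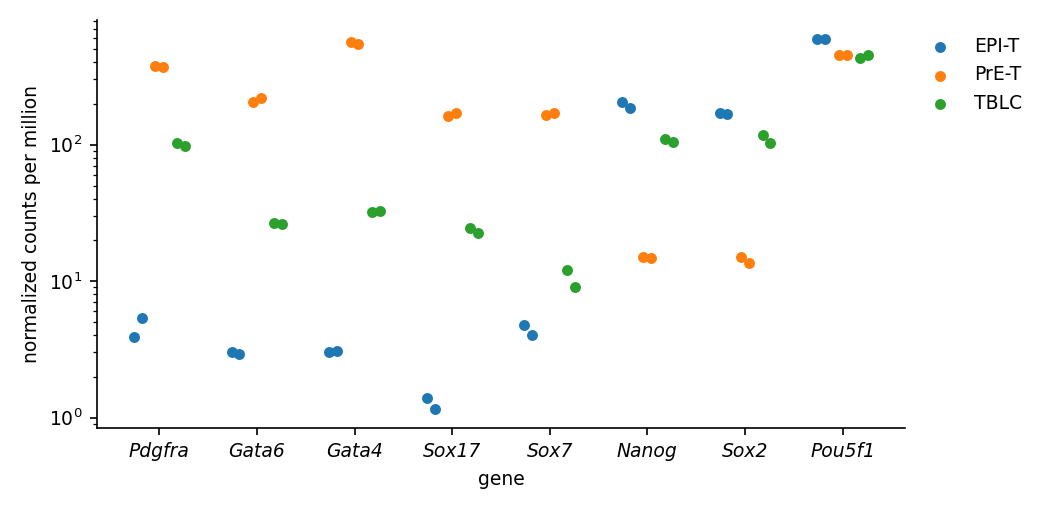
CPM of lineage genes in each library of EPI-T, PrE-T and undifferentiated TBLC. Each point is 1 library. Pdgfra encodes the antigen used to sort EPI-T from PrE-T.

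Between the sorted populations 9857 of 14373 tested genes changed, 5148 higher and 4709 lower in PrE-T, of which 2675 and 2277 did so by at least 2-fold. All 24 PrE genes were higher, with a median of 6.25 (adjusted p = 1.08e-16, or 0.0554 with an estimated correlation between genes). Col4a2 (6.78) and Dab2 (7.74 ± 0.091), an endocytic adaptor, were among them. Visceral endoderm genes were higher in 9 of 12 cases and lower in none (median 5.67, or 4.34 with uncounted members set at their bound), led by Cubn and the receptor gene Lrp2 (6.66 ± 0.069). Naive pluripotency genes split 4 higher and 16 lower of 21 (median -1.54), with Esrrb lower (-2.76 ± 0.058) and the T-box factor Tbx3 higher (3.03 ± 0.065). The 2-cell genes were lower in 19 of 22 cases (median -4.21), among them Zscan4d (-4.74 ± 0.14) and Zscan4c (-5.27 ± 0.18), which mark the brief cleavage-like state. FGF and ERK response genes were lower in 10 of 16 and higher in 3 (median -0.99), with the feedback genes Dusp6 (-2.69 ± 0.087) and Spred1 (-2.45 ± 0.069) down and Dusp4 (2.78 ± 0.086) up. Replication genes such as Mcm6 (-1.34 ± 0.055) put 12 of 20 cell cycle genes lower and 1 higher (median -0.34). By contrast, 15 of 19 cholesterol synthesis genes, including Cyp51 (1.59 ± 0.066), were higher and 1 lower (median 0.62). Cytosolic ribosomal protein genes were higher in 42 of 50 cases (43 when adjusted over the list alone), with Rpsa at 1.16 ± 0.046 and a median of 0.39. Adjusted over the list alone, the other counts were the same. Each of these lists passed at a fixed correlation, with adjusted p between 1.08e-16 and 0.00464, and none passed with an estimated one, where adjusted p lay between 0.0554 and 0.28.

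Regulators of RNA and DNA methylation also differed between PrE-T and EPI-T. Igf2bp3, which encodes an RNA-binding protein that can stabilize m6A-marked transcripts, stood at 84.9 against 42.6 CPM, and its relative Igf2bp2 rose by 1.22 ± 0.069. The reader gene Ythdf2 fell (-0.79 ± 0.06), as did the m6A writer gene Mettl14 (-1.22 ± 0.089), while Virma did not pass (-0.08 ± 0.066, adjusted p = 0.298, but -0.19 under library totals, adjusted p = 0.0182). Tet1, which oxidizes 5-methylcytosine, fell by 2.93 ± 0.052 and the imprint regulator Zfp57 by 2.23 ± 0.051. The methyltransferase genes Dnmt3b (1.42 ± 0.052) and Dnmt3a (1.41) rose. Reader genes split 3 higher and 5 lower with a median of 0.04, which turned to -0.07 under library totals. Genes typical of fibroblasts and feeder cells were higher in PrE-T in 15 of 16 cases (median 2.00, or 1.94 with bounds; adjusted p = 0.000268, or 0.0786 with an estimated correlation), with Col1a1 at 57.7 against 11.7 CPM. The sum over this list was 287 CPM in PrE-T and 82 in EPI-T. No EPI-T library held a single count of Egflam, Gpat3 or S100g, which were at least 776-fold, at least 613-fold and at least 440-fold higher in PrE-T.

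The sorted cells were next set against undifferentiated TBLC. PrE-T exceeded TBLC in Gata4 (555 ± 9.0 against 32.6 CPM, log2 4.09 ± 0.063, n = 2), Gata6 (212 against 26.5 CPM, 3.00 ± 0.075), Sox17 (2.82 ± 0.084) and Sox7 (3.97 ± 0.11). Among the largest rises Lgals2, a galectin gene, went from 0.685 to 189 CPM (8.06 ± 0.17). Cubn rose by 6.65 ± 0.075, and Amn, whose product anchors cubilin, by 5.54 ± 0.16. Nanog (14.8 against 108 CPM, -2.87 ± 0.08) and Sox2 (-2.96 ± 0.087) were lower than in TBLC and Pou5f1 was not distinguishable (0.03 ± 0.05, adjusted p = 0.594, but -0.29 under library totals). EPI-T instead held more Nanog (195 against 108 CPM, 0.85 ± 0.068), Tdgf1 (1120 against 130 CPM, 3.11 ± 0.055) and Pou5f1 (0.42 ± 0.05) than TBLC. EPI-T also held less Gata4 (-3.42 ± 0.094), Gata6 (-3.16 ± 0.11) and Sox17 (-4.19 ± 0.14), so this TBLC culture lay between the sorted populations for these genes.

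PrE-T differed from TBLC in 9670 genes, 4814 higher and 4856 lower, and 1565 and 2899 of them by at least 2-fold. Under library totals the share of higher genes dropped from 49.8% to 30.4%, and the median of all genes moved to -0.35. PrE genes were higher in 23 of 24 cases (median 3.24; adjusted p = 3.08e-17), Col4a1 (6150 against 664 CPM) and Dab2 (5.07 ± 0.075) among them. Visceral endoderm genes were higher in 11 of 12 (11 higher and 1 lower when adjusted over the list alone; median 3.85, or 3.69 with bounds). All 19 cholesterol synthesis genes rose (median 1.88), with Cyp51 (2.56 ± 0.069), as did 47 of 50 ribosomal protein genes (median 0.54). So did 14 of 17 glycolysis genes, with the glucose transporter gene Slc2a3 (2.50 ± 0.047) and Pfkl (2.89 ± 0.058). Every one of 20 cell cycle genes was higher, with Cdc6 at 1.92 ± 0.082. Naive genes split 7 higher and 11 lower, or 7 and 12 when adjusted over the list alone, with Tfcp2l1 at -3.30 ± 0.062, while Dnmt3b (3.28 ± 0.057) and Dnmt3l (2.48) rose. Lower lists were the 2-cell genes (18 of 22, median -3.65), p53 targets (14 of 20, median -0.50), including Mdm2 (-1.46 ± 0.053), and interferon response genes (13 of 17, or 15 when adjusted over the list alone). Adjusted over the list alone, all other counts were the same. With an estimated correlation the naive (adjusted p = 0.119), ribosomal (adjusted p = 0.087), 2-cell (adjusted p = 0.0503) and interferon (adjusted p = 0.087) calls did not hold, and the others named kept adjusted p = 0.0475.

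EPI-T differed from TBLC in 9327 genes, 4332 higher and 4995 lower, with a share of higher genes of 46.4% that became 33.5% under library totals (median of all genes -0.28). The rises included Myrf (4.67 ± 0.17), which encodes a membrane-bound transcription factor, and the imprinted growth-restraining genes Phlda2 (3.98 ± 0.21) and Cdkn1c (3.73 ± 0.09). Naive genes were higher in 15 of 21 cases and lower in 4, or 5 when adjusted over the list alone (median 0.59), with Utf1 at 1.93 ± 0.094 and Tbx3 lower (-2.46 ± 0.065). The 2-cell genes were higher in 12 of 22 (11 when adjusted over the list alone), Zscan4d by 1.25 ± 0.11. Cell cycle genes rose in 20 of 20 cases, with Ccne1 at 2.31 ± 0.065, and glycolysis genes in 15 of 17, with Slc2a1 at 2.50 ± 0.057 and Pgk1 at 1.82 ± 0.051. Cholesterol synthesis genes rose in 17 of 19 and spliceosome genes in 21 of 25. The p53 targets fell in 18 of 20 cases (median -1.04), among them Cdkn1a (-2.98 ± 0.092), which halts the cell cycle, and Mdm2 (-1.41 ± 0.053). PrE genes were lower in 21 of 24 (median -2.56; adjusted p = 1.87e-07). Ribosomal protein genes had a median of 0.05 that turned to -0.16 under library totals. Adjusted over the list alone, the remaining counts were unchanged. With an estimated correlation the naive (adjusted p = 0.0807) and 2-cell (adjusted p = 0.0871) calls did not hold while the others kept adjusted p of at most 0.0465. Fibroblast and feeder genes were higher in TBLC than in either sorted population, 16 of 16 against EPI-T and 15 of 16 against PrE-T. Col1a1 stood at 338 CPM in TBLC against 57.7 in PrE-T and 11.7 in EPI-T.

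The same move into SLM was seen without sorting in the 0 h libraries of the actinomycin D course of diffTBLC (3 days in SLM) and TBLC. Gata6 stood at 104 against 5.44 CPM (4.26 ± 0.067, n = 2), Gata4 at 201 against 12.7 (3.98 ± 0.052) and Pdgfra at 75.4 ± 0.053 against 15.7 ± 0.43. Sox17 (4.84 ± 0.10) and Sox7 (4.55 ± 0.094) rose. Cubn (6.70 ± 0.052), Amn (6.26 ± 0.10) and Car4 (7.24 ± 0.19), a carbonic anhydrase gene, were among the largest rises. Nanog fell from 479 to 210 CPM (-1.19 ± 0.026) and Tfcp2l1 by 2.68 ± 0.027, yet Pou5f1 rose from 991 to 1630 CPM (0.72 ± 0.02) together with the chromatin-bound pluripotency factor Utf1 (2.47 ± 0.033).

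In diffTBLC 11927 of 14463 genes changed, 6184 higher (51.8%, or 40.6% under library totals, with a median of all genes of -0.18) and 5743 lower. PrE genes were higher in 22 of 24 cases (median 3.43; adjusted p = 6.96e-12), with Col4a1 at 1350 against 128 CPM and Dab2 at 5.46 ± 0.042. So were visceral endoderm genes in 13 of 13 (median 3.44) with Lrp2 at 4.98 ± 0.041, cholesterol synthesis genes in 19 of 19 with Msmo1 at 2.04 ± 0.035, and cell cycle genes in 20 of 20. These 4 lists kept adjusted p of at most 0.00397 with an estimated correlation. Ribosomal protein genes were higher in 50 of 50 cases, with Rpl8 at 1.09 ± 0.022 and a median of 0.65 (adjusted p = 0.0603 with an estimated correlation). Formative genes were higher in 10 of 13 cases and lower in 3, including Tcf15 (3.64 ± 0.053), Dnmt3b (2.61 ± 0.033) and Etv4 (2.60; adjusted p = 0.0774 with an estimated correlation). Fibroblast genes fell in 12 of 16 cases and rose in 3 (adjusted p = 0.117 with an estimated correlation), with Dcn, a matrix proteoglycan gene, at -4.13 ± 0.12 and the smooth muscle gene Tagln at 2.73. Naive genes split 8 higher and 12 lower of 21 and did not pass as a list (adjusted p = 0.141). Among single genes the steepest falls were Trpm1 (-6.95 ± 0.21) and the cystine transporter gene Slc7a11 (-5.89 ± 0.20), and Virma fell from 83.1 to 54.3 CPM (-0.61 ± 0.041). Lgals2 was 882-fold higher in diffTBLC, with a counting interval from 301 to 4280. Adjusted over the list alone, these list counts were the same.

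After only 8 h in SLM (TBLC_PlaB-) the transcriptome stayed close to that of TBLC_Ctrl. None of the PrE factors passed: Gata6 was at 0.02 ± 0.14, Gata4 at -0.08 ± 0.12 and Pdgfra at 0.00 ± 0.088 (n = 2), and Nanog was at -0.03 ± 0.026 (adjusted p = 0.807). The spliceosomal gene Lsm2 (0.46 ± 0.042) and the phosphatase gene Ppp1cb (0.46 ± 0.034) rose most, joined by Zscan4e (0.38 ± 0.061), the Notch ligand gene Jag1 (0.33 ± 0.073) and the naive factors Klf4 (0.19 ± 0.032) and Klf5 (0.18 ± 0.027). Jag1 did not pass without replicate 1 of TBLC_Ctrl (adjusted p = 0.0759) or of TBLC_PlaB- (adjusted p = 0.0741) at 0 h. At 0 h 177 of 14107 genes passed, 110 higher and 67 lower, and DESeq2 counted 73. Without replicate 2 of TBLC_Ctrl at 0 h the count was 70. Mitochondrial-encoded genes fell in 6 of 13 cases (9 when adjusted over the list alone; median -0.16; adjusted p = 1.19e-23, or 0.0126 with an estimated correlation), with mt-Atp6 at -0.87 ± 0.12 and mt-Co2 at -0.79 ± 0.11. Ribosomal protein genes fell in 7 of 50 (2 higher and 12 lower when adjusted over the list alone; median -0.02), among them Rpl10 (-0.14 ± 0.022, but 0.00 over 1 to 3 h). Naive genes split 3 higher and 2 lower of 21 (4 and 2 when adjusted over the list alone). No PrE gene passed over all genes, and the list median was -0.01. When the arm difference was averaged over the 1 to 3 h libraries of the same course, 2918 genes passed, glycolysis genes were lower in 13 of 17 cases (median -0.20; adjusted p = 1.36e-41, or 4.29e-05 with an estimated correlation) and FGF and ERK response genes higher in 7 of 16.

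To ask whether the m6A writers support the PrE program, diffTBLC given siRNA against Mettl3, the catalytic subunit, or Virma, the scaffold of the writer complex, were compared with siNC at steady state. Virma stood at 84.0 ± 4.3 CPM in siVirma against 118 ± 5.2 in siNC (-0.50 ± 0.085, adjusted p = 1.88e-06). In the libraries labelled siMettl3, Mettl3 was not distinguishable from siNC, at 26.9 ± 0.76 against 30.4 ± 1.1 CPM (-0.18 ± 0.15, adjusted p = 0.771). Gata4 and Pdgfra were lower in both. In siVirma, Gata6 stood at 58.4 ± 4.8 against 126 ± 1.6 CPM (-1.11 ± 0.093, n = 2) and Pdgfra at 67.8 ± 1.9 against 133 ± 3.0 (-0.98 ± 0.089). Gata4 (-0.86 ± 0.067), Sox17 (-0.94 ± 0.15) and Sox7 (-0.99 ± 0.12) were down as well. In the libraries labelled siMettl3, Pdgfra (96.0 ± 5.9 CPM, -0.47 ± 0.082), Gata4 (-0.37 ± 0.062) and Gata6 (-0.35 ± 0.083) fell, and Sox17 (-0.39 ± 0.14, adjusted p = 0.202) and Sox7 (-0.34 ± 0.10, adjusted p = 0.094) did not pass. The call of Gata6 there was lost without replicate 2 of siMettl3 (-0.26, adjusted p = 0.426) and without either replicate of siNC (adjusted p = 0.0886 and 0.152). Nanog (0.18 ± 0.062 in siVirma, adjusted p = 0.0573), Sox2 and Pou5f1 did not pass in either.

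**Figure D2:**
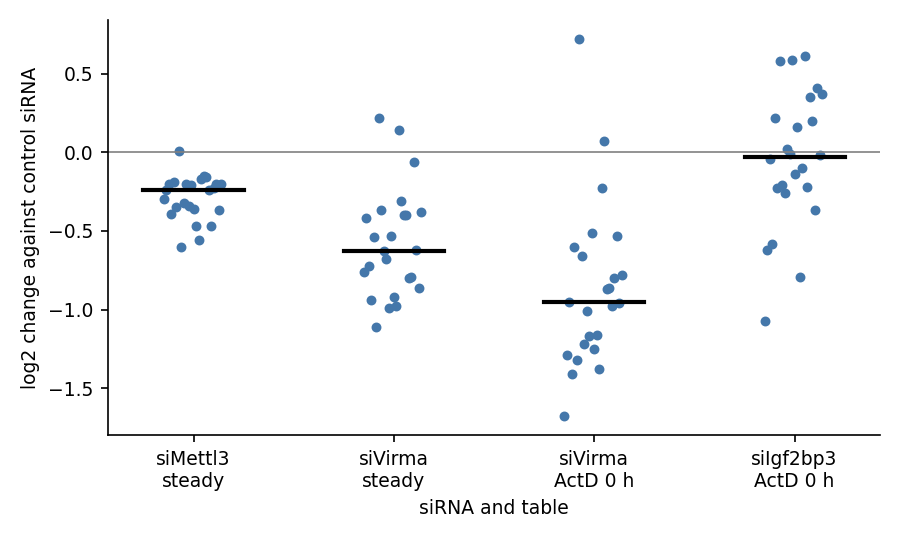
Log2 change of each measured PrE list gene against the control siRNA of the same table. Each point is 1 gene, the bar is the median, and the tables were normalized separately.

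In siVirma 863 of 12141 genes passed, 422 higher and 441 lower, 29 and 28 of them by at least 2-fold, and DESeq2 counted 279. Without replicate 2 of siNC the count was 495. PrE genes fell in 18 of 24 cases (19 when adjusted over the list alone; median -0.62; adjusted p = 3.26e-109, or 0.00308 with an estimated correlation) and 1 rose. Fibroblast and feeder genes, a list also higher in PrE-T than in EPI-T, fell in 3 of 15 cases, Fbln2 (-0.31 ± 0.062), Col1a1 (-0.29 ± 0.062) and Col5a2 (-0.29 ± 0.084), and no count changed when adjusted over the list alone (median -0.16; adjusted p = 0.00605, or 0.158 with an estimated correlation). The call of Col1a1 was lost without replicate 1 of siNC (-0.18; adjusted p = 0.211). That of Col5a2 was lost without replicate 1 of siVirma (adjusted p = 0.336), without either replicate of siNC (adjusted p = 0.075 and 0.109) and in DESeq2 (adjusted p = 0.186). The falls covered basement membrane genes, with Lama1 at 1200 against 1980 CPM (-0.72 ± 0.028), Col4a1 at 1440 against 2210 (-0.62 ± 0.026) and Lamb1 at -0.68 ± 0.033, and the adaptor gene Dab2 (-0.80 ± 0.043). Visceral endoderm genes fell in 6 of 10 cases (median -0.41; adjusted p = 1.43e-30, or 0.0129 with an estimated correlation), including Apoe (-0.52 ± 0.048), Cubn (-0.53 ± 0.03) and Lrp2 (-0.38 ± 0.031). Bmp6 (-1.31 ± 0.24), the BMP modulator gene Bmper (-1.24 ± 0.20) and the retinol transporter gene Stra6 (-1.22 ± 0.27) were among the largest falls, and the kinase gene Stk26 (1.59 ± 0.31) was among the largest rises. Stra6 did not pass without replicate 2 of siNC (-0.96, adjusted p = 0.0698) or of siVirma (-0.92, adjusted p = 0.0666). Immediate early genes were lower in 7 of 26 (1 higher and 8 lower when adjusted over the list alone), with Fosb at -1.39 ± 0.35 and Junb at -0.44 ± 0.11. Neither passed without replicate 1 of siVirma (adjusted p = 0.0709 and 0.0648), nor did Junb in DESeq2 (adjusted p = 0.0579). Glycolysis genes were higher in 5 of 17 and lower in 1 (7 and 1 when adjusted over the list alone), with Slc2a1 at 0.35 ± 0.041. Both lists lost the call with an estimated correlation (adjusted p = 0.158). Naive genes split 2 higher and 5 lower (6 and 6 when adjusted over the list alone), with Tdgf1 up (0.30 ± 0.039) and Tbx3 down (-0.67 ± 0.075). As a list their median was 0.04 and their mean 0.03 while the test pointed down (adjusted p = 0.662). The writer partner gene Wtap (0.30 ± 0.08) and Tet1 (0.31 ± 0.032) rose. The call of Wtap was lost without replicate 1 of siNC (adjusted p = 0.132), without replicate 2 of siVirma (adjusted p = 0.143) and in DESeq2 (adjusted p = 0.108).

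Fewer genes passed in the libraries labelled siMettl3, 105 in all with 50 higher and 55 lower, 4 of them by at least 2-fold, and DESeq2 counted 48. Leaving out replicate 1 of siMettl3 gave 41. The PrE list was nevertheless lower, with 12 of 24 genes down (19 when adjusted over the list alone; median -0.24; adjusted p = 2.77e-57, or 0.00672 with an estimated correlation). Visceral endoderm genes fell in 5 of 10 cases (8 when adjusted over the list alone; adjusted p = 0.0104 with an estimated correlation), with Apoe at -0.34 ± 0.046. Mitochondrial-encoded genes fell in 5 of 12 (7 when adjusted over the list alone; adjusted p = 0.00672 with an estimated correlation), with mt-Nd6 at 366 against 624 CPM (-0.77 ± 0.043). Col4a1 (-0.20 ± 0.026), Cubn (-0.21 ± 0.029) and Pga5 (-0.77 ± 0.18), a pepsinogen gene, fell. Esrrb (0.21 ± 0.054), Tet1 (0.26 ± 0.032), Lefty1 (0.28 ± 0.078) and Chd7 (0.40 ± 0.086) rose. Esrrb did not pass without any 1 of the 4 libraries (adjusted p = 0.122 to 0.299) or in DESeq2 (adjusted p = 0.0568). Lefty1 did not pass without replicate 2 of siMettl3 (0.17, adjusted p = 0.664) or either replicate of siNC (adjusted p = 0.169 and 0.359). Pga5 was lost without either replicate of siMettl3 (adjusted p = 0.101 and 0.19) or replicate 1 of siNC (adjusted p = 0.185). Chd7 was lost without replicate 1 of siMettl3 (adjusted p = 0.187) or replicate 2 of siNC (adjusted p = 0.166). Of the calls of siVirma and of the libraries labelled siMettl3, 36 genes were higher and 43 lower in both, against 1.7 and 2.0 by product. Both share the siNC libraries, which the product ignores. Their correlation of 0.51 has a simulated floor of 0.48, so the excess of shared calls stays open.

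Genes at least 4-fold higher in PrE-T than in EPI-T were also followed as a set. Of 1015 such genes, 189 fell and 4 rose in siVirma (median -0.29; camera p = 5.95e-23, or p = 0.000122 with an estimated correlation). In the libraries labelled siMettl3, 32 fell and 2 rose (median -0.16; camera p = 1.04e-13, or p = 0.000277 with an estimated correlation). Of 735 genes at least 4-fold higher in EPI-T, 64 rose and 15 fell in siVirma, including Lef1 (0.82 ± 0.19) and Lin28b (0.50 ± 0.11). Lef1 did not pass without replicate 2 of siNC (0.70, adjusted p = 0.0582) or in DESeq2 (adjusted p = 0.0571), and Lin28b did not without replicate 1 of siVirma (0.36, adjusted p = 0.125).

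A separate actinomycin D table held siVirma and its own control siNC1, and another held siIgf2bp3 and siNC2, so these effects could be read at 0 h and over 1 to 3 h. Virma was lower in siVirma by 0.27 ± 0.061 at 0 h (34.1 against 41.2 CPM, n = 2, but -0.08 under library totals, adjusted p = 0.288) and by 1.04 ± 0.035 on average over 1 to 3 h. In the libraries labelled siIgf2bp3, Igf2bp3 was higher than in siNC2 at 0 h, at 27.0 ± 2.5 against 18.3 ± 2.3 CPM (0.56 ± 0.079), and lower over 1 to 3 h (-0.58 ± 0.041). Virma there went from 0.48 ± 0.065 at 0 h (0.30 without replicate 2 of siNC2 at 0 h) to -0.51 ± 0.036. Ribosomal protein genes shared the turn: against siNC1 they were lower in siVirma in 50 of 50 cases at 0 h (median -0.81) and higher in 47 over 1 to 3 h (median 0.27). Against siNC2 they were lower in 50 of 50 (median -0.80) and then higher in 50 (median 0.74).

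**Figure D3:**
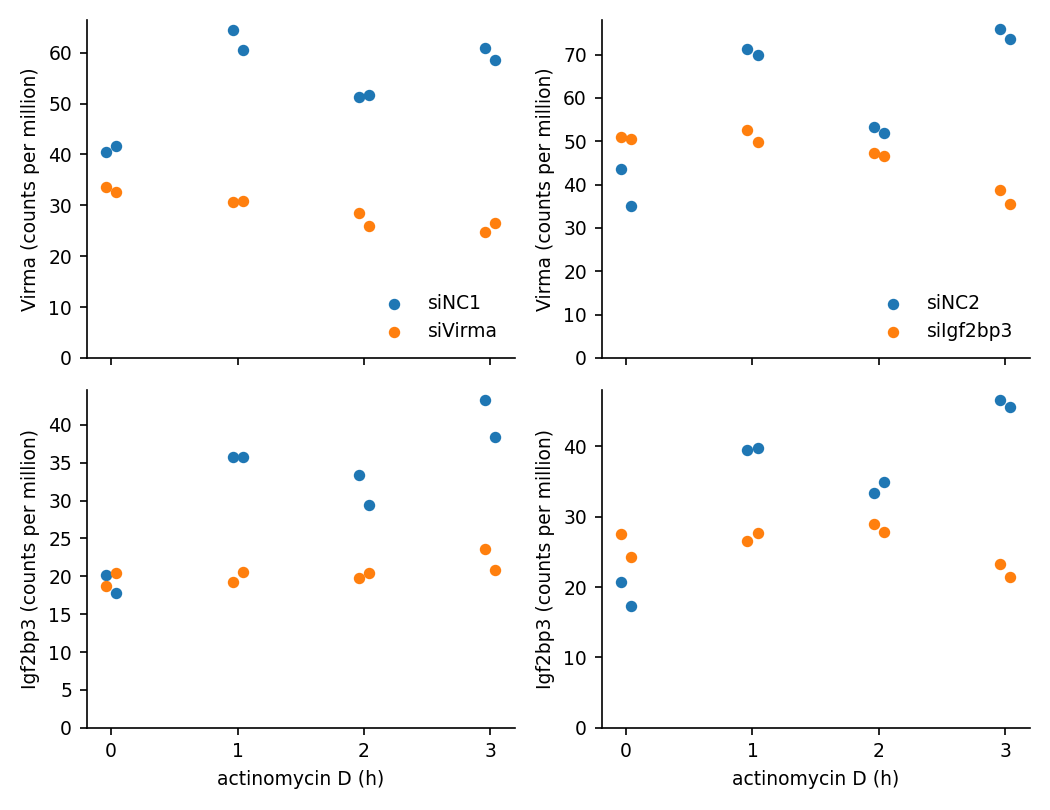
Virma and Igf2bp3 in each library of the siVirma and siIgf2bp3 actinomycin D tables by hour. Each point is 1 library, and the tables were normalized separately.

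PrE factors were lower in siVirma at every hour. Gata6 stood at 35.8 against 89.4 CPM at 0 h (-1.32 ± 0.059, n = 2) and averaged -1.50 ± 0.045 over 1 to 3 h. Gata4 measured -0.96 ± 0.048 and -1.34 ± 0.03, Sox17 -1.41 ± 0.077 and -0.82 ± 0.082, and Pdgfra -1.16 ± 0.068 and -1.96 ± 0.041. The PrE list was lower in 21 of 24 cases and higher in 1 at 0 h (22 and 1 when adjusted over the list alone; median -0.95; adjusted p = 5.95e-14, or 0.00194 with an estimated correlation). It was lower in 23 over 1 to 3 h (median -1.23; adjusted p = 1e-14, or 0.0015 with an estimated correlation). Visceral endoderm genes fell in 10 of 13 cases at 0 h (median -0.64; adjusted p = 3.66e-06, or 0.0078 with an estimated correlation), with Apoe at -1.22 ± 0.049 and Amn at -1.68. The laminin genes Lama1 (-0.95 ± 0.04) and Lamb1 (-1.01 ± 0.044) fell with them. In all 8242 of 13664 genes passed at 0 h, 4520 higher and 3722 lower, a share of 54.8% that became 74.4% under library totals (median of all genes 0.24). Naive genes split 4 higher and 10 lower with a median of -0.09 that turned to 0.11 under library totals, and Dppa5a fell by 1.18. Integrin gene Itga6 (2.48 ± 0.097) and the DNA glycosylase gene Tdg (1.81) rose most at 0 h but were lower over 1 to 3 h (-1.36 and -0.86), and the fall of Dppa5a was gone at 1 h (0.08). Stress response genes, among them Psat1 (0.79 ± 0.041) and Ddit4 (1.13 ± 0.061), were higher in 9 of 17 cases and lower in 1 at 0 h (adjusted p = 0.0572). Over 1 to 3 h they were higher in 16 (median 0.48; adjusted p = 3.73e-07, or 0.00988 with an estimated correlation). Across 12045 genes the 0 h effect of siVirma and that at steady state, from separately normalized tables, correlated at 0.34. In both, 335 genes were higher and 317 lower, against 150.9 and 127.7 by product, and 64 were of opposite sign. With the effect averaged over 1 to 3 h the correlation was 0.33, 224 were higher and 356 lower in both, against 148 and 172.7 by product, and 189 were of opposite sign.

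The libraries labelled siIgf2bp3 showed PrE genes on both sides at 0 h. Gata6 (-0.23 ± 0.052, n = 2) and Sox17 (-0.58 ± 0.064) were lower. Gata4 did not pass (-0.02 ± 0.04, adjusted p = 0.603), though it did in a fit of the 4 libraries alone (-0.15, adjusted p = 0.0014). Pdgfra passed at 0.16 ± 0.06, but not in DESeq2 (0.08, adjusted p = 0.389) or in the 4 libraries alone (0.03, adjusted p = 0.676). Its call was also lost without replicate 1 of siIgf2bp3 (0.09, adjusted p = 0.276) or either replicate of siNC2 (0.14 and 0.09, adjusted p = 0.126 and 0.344) at 0 h, and without any 1 library of siIgf2bp3 at 2 or 3 h (adjusted p = 0.0689 to 0.102). PrE genes split 9 higher and 8 lower of 24 (median -0.03, turning to 0.05 under library totals; adjusted p = 0.732). Lamc1 (0.61 ± 0.04) and Cubn (0.59 ± 0.043) rose at 0 h and turned to -0.87 and -0.75 over 1 to 3 h. Amn went from -1.07 ± 0.061 to 0.56 and Pou5f1 from -0.36 ± 0.05 to 0.45, while Sox2 was higher at 0 h (0.61 ± 0.041) and at 0.03 over 1 to 3 h. Over 1 to 3 h Pdgfra (-0.84 ± 0.036), Gata4 (-0.40 ± 0.025), Gata6 (-0.38 ± 0.038) and Sox7 (-0.35 ± 0.079) were lower, and Sox17 was level (0.00 ± 0.09). The list was lower in 18 of 24 cases and higher in 3 (median -0.39; adjusted p = 0.000355, or 0.0381 with an estimated correlation). At 0 h 8928 of 13580 genes passed, 5590 higher (62.6%, or 69.5% under library totals, with a median of all genes of 0.22) and 3338 lower. Itga6 (2.99 ± 0.069) and the isopentenyl isomerase gene Idi1 (2.11 ± 0.083) rose at 0 h and stood at -1.93 and -1.29 over 1 to 3 h. Rplp1 (-1.29 ± 0.034) fell and then stood at 1.04. Of 1162 PrE-T-high genes 519 fell and 125 rose in siVirma at 0 h (median -0.31). In the libraries labelled siIgf2bp3 327 of 1168 fell and 258 rose, with a median of -0.01 against 0.15 for other genes (camera p = 0.0045, or p = 0.000158 with an estimated correlation). Over 1 to 3 h the median there was -0.09 and the set did not pass (camera p = 0.422, or p = 0.0951 with an estimated correlation).

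RIP from TBLC after 3 days in SLM was compared with its input. Without a mock pulldown, binding to the readers cannot be told from other recovery. Igf2bp3 RIP was rich in PrE transcripts: Cubn measured 5610 against 1050 CPM (2.42 ± 0.0052, n = 2), and Dab2 2260 against 578 (1.97 ± 0.016). Apob, which encodes a lipid carrier, was at 2.73 ± 0.057, Sox7 at 1.17 ± 0.067, Pdgfra at 0.75 ± 0.049, Gata4 at 0.60 ± 0.036 and Gata6 at 0.36 ± 0.059. Nanog (-1.14 ± 0.052), Pou5f1 (-1.06 ± 0.03), Dppa5a (-2.48 ± 0.036) and Sox17 (-0.53 ± 0.11) were depleted. In total 8997 of 12904 genes passed, 4512 higher (50.2%, or 37.0% under library totals, with a median of all genes of -0.21) and 4485 lower. PrE genes were higher in 16 of 24 cases and lower in 5 (median 0.61; adjusted p = 1.01e-24, or 0.153 with an estimated correlation). Naive genes were higher in 5 and lower in 12 of 21 (median -0.51; adjusted p = 0.411 with an estimated correlation). Ribosomal protein genes were lower in 49 of 50 (median -1.36; adjusted p = 0.165 with an estimated correlation), Rplp1 falling from 1490 to 209 CPM and Rpl4 alone rising (0.44). Spliceosome genes split 7 higher and 17 lower (adjusted p = 0.304 with an estimated correlation), with Srsf3 at -1.84 and Prpf8 at 0.87. Visceral endoderm genes, 5 higher and 4 lower, had a median of 0.10 that turned to -0.10 under library totals. Adjusted over the list alone, these counts were the same. The largest rises were the interferon genes Ifi207 (4.89 ± 0.17) and Oas3 (4.73 ± 0.21), the Notch coactivator gene Maml2 (4.70 ± 0.20) and Klf11 (4.50 ± 0.044), and Tet1 was at 1.53 ± 0.013. Of 1158 PrE-T-high genes 527 were higher and 213 lower (median 0.34; camera p = 0.0127, or p = 0.0153 with an estimated correlation).

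Ythdf2 RIP carried its own transcript and those of its relatives, with Ythdf2 at 337 against 88.7 CPM (1.92 ± 0.073, n = 2), Ythdf1 at 2.26 and Ythdf3 at 2.00. Writer genes were higher in 7 of 9 cases and lower in 2 (median 0.79; adjusted p = 0.03, or 0.361 with an estimated correlation), with Virma at 247 against 59.6 CPM (2.05 ± 0.081) and Rbm15b at 2.96 ± 0.11. FGF and ERK response genes were higher in 13 of 16 and lower in 2 (median 1.03; adjusted p = 0.361 with an estimated correlation), among them the feedback inhibitor genes Spry4 (2.67 ± 0.12) and Spry2 (2.40 ± 0.084). Immediate early genes were higher in 16 of 25 and lower in 4 (adjusted p = 0.446 with an estimated correlation), led by Junb (2.63 ± 0.10) and the cytokine inhibitor gene Socs3 (1.67 ± 0.059). Fgf4, the ligand that drives PrE choice, was at 2.85 ± 0.059, Sox2 at 1.32 ± 0.061 and Gata6 at 2.07 ± 0.23. Pou5f1 (494 against 1620 CPM, -1.72 ± 0.045) and Nanog (99.9 ± 1.3 CPM in the input, adjusted p = 2.88e-16) were lower. Ribosomal protein genes were lower in 50 of 50 cases (median -2.47; adjusted p = 0.177 with an estimated correlation), Rplp1 at -3.47 ± 0.047. Lower too were glycolysis genes in 13 of 17 with 4 higher, Gapdh at -3.01 ± 0.048, and cell cycle genes in 14 of 20 with 3 higher (both adjusted p = 0.361 with an estimated correlation). PrE genes split 10 higher and 5 lower of 23 (median 0.38; adjusted p = 0.70), with Lamc1 up (1.13 ± 0.045) and Sparc down (-2.03 ± 0.058). Adjusted over the list alone, the counts did not differ. In all 9764 of 12364 genes passed, 4969 higher and 4795 lower. The effects of the 2 RIPs, from separately normalized tables, correlated at 0.41. The Ythdf2 input held 5.65 CPM of Gata6 and its PrE list summed to 3070 CPM, against 13200 in the Igf2bp3 input.

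Stability was read as the slope of each gene over 0 to 3 h of actinomycin D, in log2 units per hour relative to the centre of all transcripts. A lower slope in one arm can therefore reflect a decline there or a relative rise in the other. Between diffTBLC and TBLC the clearest anchor was Nanog, which declined in TBLC (-0.26 per hour) and held level in diffTBLC (0.03; difference 0.30 ± 0.032, adjusted p = 2.25e-05, n = 2 per hour). Gata6 lost ground in both, at -0.50 and -0.63 per hour, without a difference (0.14 ± 0.096, adjusted p = 0.421), and neither Gata4 (0.10 ± 0.066, adjusted p = 0.377) nor Pdgfra (-0.08, adjusted p = 0.399) passed. Between 3 h and 0 h alone Gata6 (1.02, adjusted p = 0.000227) and Gata4 (0.42, adjusted p = 0.00834) did pass, as did Pdgfra without 0 h (-0.18, adjusted p = 0.0105). Short-lived transcripts had higher slopes in diffTBLC in 9 of 26 cases and lower ones in none (12 when adjusted over the list alone; median 0.26; adjusted p = 3.15e-08, or 0.285 with an estimated correlation), including the growth-factor response genes Egr1 (0.85 ± 0.21, but -0.11 without the 0 h libraries), Dusp1 (0.72 ± 0.15) and Fos (1.49 ± 0.24). From 0 to 1 h the list fell more in diffTBLC (-1.32 against -0.82), then less. Without 0 h Dusp1 (0.39, adjusted p = 0.0538) and Fos (0.17, adjusted p = 0.701) did not pass. Nor did Dusp1 and Egr1 in DESeq2 (adjusted p = 0.0719 and 0.0895), or Egr1 scaled to ribosomal protein genes (adjusted p = 0.076) and without either replicate of TBLC at 0 h (adjusted p = 0.0573 and 0.0583). Mitochondrial-encoded genes such as mt-Cytb (-0.28 ± 0.036) were lower in 4 of 11 cases (5 when adjusted over the list alone; adjusted p = 0.285 with an estimated correlation). Zfp397 (-0.47 ± 0.038), Zfp948 (-0.44 ± 0.038), Sesn2 (-0.43 ± 0.029) and Inhbb (-0.53 ± 0.077) had lower slopes in diffTBLC. Fst (0.34 ± 0.05) and Rbm15 (0.35 ± 0.048) had higher ones. PrE genes split 1 higher and 1 lower of 24 (2 and 3 when adjusted over the list alone; median -0.06), with Sparc lower (-0.08 ± 0.023). The call of Sparc was lost in 12 of 16 fits without 1 library, with -0.03 and -0.02 without replicate 1 or 2 of diffTBLC at 3 h (adjusted p = 0.569 and 0.739), and in DESeq2 (adjusted p = 0.122). In all 1188 genes passed, 370 higher (31.1%, but 53.2% in DESeq2 and 71.4% when scaled to ribosomal protein genes) and 818 lower. The count was 4728 without 0 h and 630 without replicate 2 of TBLC at 3 h.

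Between TBLC_PlaB- and TBLC_Ctrl 58 slopes passed, 45 higher and 13 lower, and Gata6 (0.00 ± 0.10), Pdgfra (0.05) and Nanog (0.03 ± 0.018, adjusted p = 0.473) were not among them. Slopes were lower in TBLC_PlaB- for Ndufa4l2 (-0.67 ± 0.10), Bnip3 (-0.30 ± 0.046) and the lactate transporter gene Slc16a3 (-0.28 ± 0.061), which ran at -0.26, -0.08 and -0.08 per hour there and at 0.41, 0.23 and 0.20 in TBLC_Ctrl. That of Pfkp was 0.03 against 0.16 (-0.13 ± 0.021). Without 0 h Bnip3 (-0.14, adjusted p = 0.073), Pfkp (-0.06, adjusted p = 0.105) and Slc16a3 (-0.02, adjusted p = 0.867) did not pass, and Slc16a3 did not in 11 of 16 fits without 1 library (adjusted p = 0.0535 to 0.153). Glycolysis genes were lower in 2 of 17 cases (6 when adjusted over the list alone; median -0.03; adjusted p = 6.66e-08, or 0.127 with an estimated correlation). The splicing kinase gene Clk1 declined in both, at -0.72 and -0.39 per hour (-0.32 ± 0.033). Ribosomal protein genes were higher in 2 of 50 (14 when adjusted over the list alone; adjusted p = 2.2e-18, or 0.40 with an estimated correlation), with Rplp0 at 0.10, which did not pass without any 1 of the 4 libraries at 3 h (adjusted p = 0.137 to 0.159). Tmem119 (0.23 ± 0.05), the protease gene Prss23 (0.20 ± 0.039) and S100a6 (0.20 ± 0.039) had higher slopes. Tmem119 did not pass in 10 of 16 fits without 1 library (adjusted p = 0.0526 to 0.218), and S100a6 did not without any 1 library at 3 h (adjusted p = 0.117 to 0.146). Prss23 did not pass without either replicate of TBLC_Ctrl (adjusted p = 0.0904 and 0.09) or replicate 2 of TBLC_PlaB- (adjusted p = 0.103) at 3 h. Scaled to ribosomal protein genes neither Rplp0 nor these 3 passed (adjusted p = 0.0605 to 0.301), nor did Tmem119 under library totals (adjusted p = 0.0763). As a set, genes 4-fold higher in PrE-T than in EPI-T had higher slopes in 11 of 1198 cases and lower in none (camera p = 0.000457, or p = 0.0467 with an estimated correlation), in 204 and 11 without 0 h (camera p = 0.000253, or p = 0.00123 with an estimated correlation). Over 1 and 2 h alone they did not pass at a fixed correlation (camera p = 0.139, or p = 0.0138 with an estimated one). Genes 4-fold higher in EPI-T had lower slopes in 4 of 1005 cases (camera p = 0.000303, or p = 0.000128 with an estimated correlation), though not over 1 and 2 h alone at a fixed correlation (camera p = 0.202, or p = 0.0155 with an estimated one). DESeq2 counted 203, scaling to library totals 27 with 55.6% higher against 77.6% here. The count ran from 8 without replicate 2 of TBLC_Ctrl at 3 h to 179 without replicate 1 of TBLC_Ctrl at 0 h.

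For siVirma against siNC1, Virma itself had a lower slope (-0.27 ± 0.066, adjusted p = 0.0356, n = 2 per hour), at -0.15 per hour against 0.13 in siNC1. Among PrE transcripts Dab2 (-0.31 ± 0.069), Col4a1 (-0.29 ± 0.076), Col4a2 (-0.23) and Nid2 (-0.18) had lower slopes. Scaled on all genes, Dab2 stood at 162 CPM at 0 h and 158 at 3 h in siVirma while it went from 300 to 589 in siNC1. The factors did not pass: Pdgfra was at -0.24 ± 0.095 (adjusted p = 0.0849), Gata4 at -0.12 ± 0.071 (adjusted p = 0.201) and Gata6 at -0.07 ± 0.071 (adjusted p = 0.458). The list was lower in 5 of 24 cases (1 higher and 7 lower when adjusted over the list alone; median -0.14; adjusted p = 0.0722). Ribosomal protein genes were higher in 4 of 50 (42 when adjusted over the list alone; median 0.33; adjusted p = 2.33e-14, or 0.619 with an estimated correlation). Over 1 and 2 h alone Virma (0.11), Dab2 (0.02), Col4a1 (0.16), Col4a2 (0.14) and Nid2 (0.07) no longer pointed down. Their calls were lost in 11 of 16 fits without 1 library for Dab2 and in 12 for each of the others (adjusted p = 0.0519 to 0.156), and in all 5 under library totals and with no filter. Pdgfra passed without replicate 1 or 2 of siNC1 at 1 h (adjusted p = 0.0147 and 0.0282), and between 3 h and 0 h alone it (-0.84) and Gata4 (-0.43) did. Of 13664 genes 1221 passed, 398 higher and 823 lower, but the count hangs on single libraries: no gene passed in edgeR without replicate 1 of siNC1 at 0 h, and 5126 without its replicate 1 at 1 h. No gene passed either with the 0 h libraries left out (497 at an unadjusted p under 0.05), 1 under library totals and 3172 in DESeq2.

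The libraries labelled siIgf2bp3 differed from siNC2 in 7110 slopes, 3584 higher (50.4%, or 28.5% under library totals and 1.7% when scaled to ribosomal protein genes) and 3526 lower. Igf2bp3 (-0.37 ± 0.12, adjusted p = 0.016, n = 2 per hour), Virma (-0.34 ± 0.11), Pdgfra (-0.31 ± 0.13, adjusted p = 0.0499) and the basement membrane gene Nid2 (-0.34 ± 0.077) had lower slopes. From 0 to 3 h, scaled on all genes, Igf2bp3 went from 25.8 to 22.4 CPM against 19 to 46 in siNC2, Virma from 50.8 to 37.2 against 39.4 to 74.7 and Pdgfra from 50 to 27.8 against 48.6 to 66.9. Slopes were higher for Sox17 (0.25 ± 0.082), Amn (0.73 ± 0.13) and Pou5f1 (0.33 ± 0.086), which went from 1560 to 3180 CPM against 2160 to 2070, and Gata6 (-0.03, adjusted p = 0.739, but -0.57 when scaled to ribosomal protein genes, adjusted p = 0.0275) did not pass. The call of Pdgfra was lost in 10 of 16 fits without 1 library (adjusted p = 0.0504 to 0.102). That of Sox17 was lost under library totals (0.12, adjusted p = 0.216) and without replicate 2 of siIgf2bp3 at 0 h or its replicate 1 at 3 h (adjusted p = 0.0564 and 0.0601), and that of Amn when scaled to ribosomal protein genes (0.10, adjusted p = 0.148). Over 1 and 2 h alone the differences of Igf2bp3 (0.30), Virma (0.31), Pdgfra (0.31), Nid2 (0.13), Pou5f1 (-0.28), Sox17 (-0.10) and Amn (-0.28) had the opposite sign. PrE genes split 6 higher and 8 lower of 24 (6 and 9 when adjusted over the list alone; median -0.14; adjusted p = 0.518). Ribosomal protein genes were higher in 50 of 50 cases (median 0.67; adjusted p = 0.843 with an estimated correlation), with Rplp2 at 1.12 ± 0.19 (-0.36 over 1 and 2 h). Itga6 (-1.57 ± 0.43) and Idi1 (-1.22 ± 0.29), both high at 0 h, had lower slopes, at 0.59 and 0.17 over 1 and 2 h. From 2 to 3 h the ribosomal protein list changed by 0.74 in these libraries and by -0.27 in siNC2. Without the 0 h libraries no slope passed, although 3231 had an unadjusted p under 0.05.

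**Figure D4:**
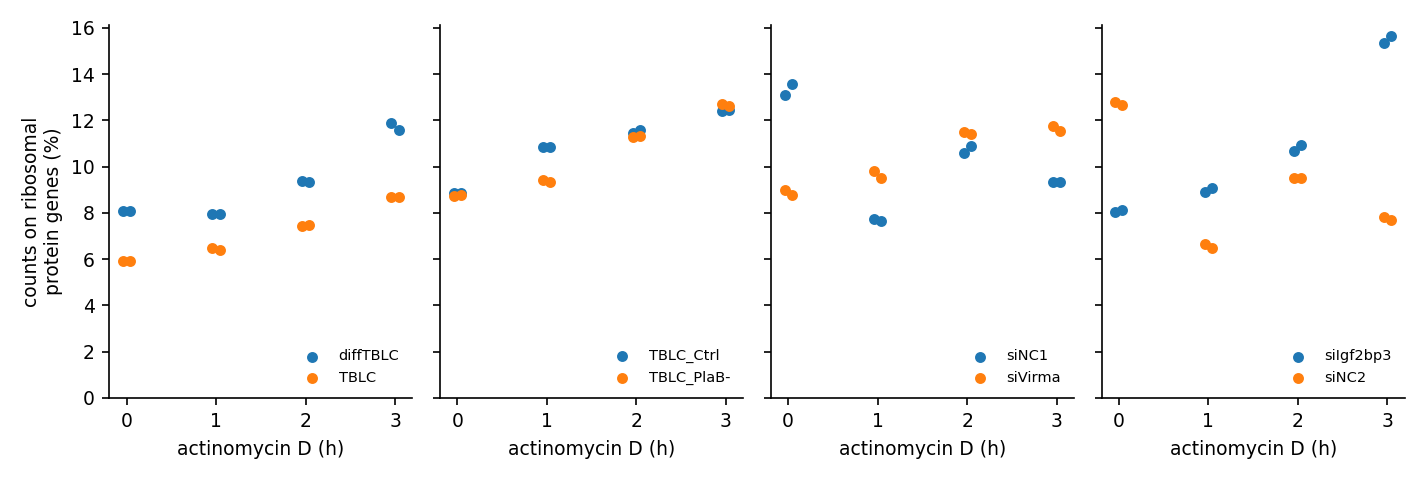
Share of counts on cytosolic ribosomal protein genes in each library of the 4 actinomycin D courses by hour. Each point is 1 library.

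Transcripts at least 2-fold enriched in Igf2bp3 RIP were then followed through the slopes. In the libraries labelled siIgf2bp3, 418 of 1198 such genes, Dab2 (-0.32, from 362 to 342 CPM against 308 to 688 in siNC2) among them, had lower slopes and 41 higher ones, with a median of -0.22 against -0.01 for other genes (camera p = 3.45e-09, or p = 0.316 with an estimated correlation). Without 0 h the median was -0.06 against 0.05 (camera p = 5.93e-05, or p = 0.485 with an estimated correlation), and over 1 and 2 h the set turned to a median of 0.23 (camera p = 1.95e-11, or p = 0.00403). In siVirma 52 of 1195 were lower and 4 higher (median -0.12; camera p = 3.22e-06, or p = 0.262 with an estimated correlation). Without 0 h none passed in edgeR and the median was -0.03, and over 1 and 2 h 162 were higher and 7 lower (median 0.16; camera p = 1.55e-09, or p = 0.00559 with an estimated correlation). At a fixed correlation this 2-fold set did not pass in diffTBLC (29 higher and 81 lower of 1276, camera p = 0.483) or in TBLC_PlaB- (4 higher and none lower of 1257, camera p = 0.994), but it pointed down with hours left out. In diffTBLC 60 were higher and 296 lower without 0 h (camera p = 0.000564, or p = 0.0368 with an estimated correlation), and 39 and 98 over 1 and 2 h (camera p = 3.09e-05, or p = 0.0012). In TBLC_PlaB- 68 were higher and 158 lower without 0 h (camera p = 0.000715, or p = 0.0523 with an estimated correlation), and 9 and 156 over 1 and 2 h (camera p = 5.17e-06, or p = 8.84e-05). Against 10000 random lists matched on expression, as a description of these libraries, no list had a lower median than the set in siIgf2bp3, siVirma or diffTBLC (-0.04 against -0.017 as the middle of the lists), and in TBLC_PlaB- the set stood at percentile 37.98. Without 0 h none had a lower one in siIgf2bp3, diffTBLC and TBLC_PlaB-, and in siVirma the set stood at percentile 18.26. With genes enriched at any fold the set pointed down and passed at a fixed correlation in diffTBLC (128 higher and 368 lower of 4472, camera p = 0.00472, or p = 0.418 with an estimated correlation) and in TBLC_PlaB- (8 higher and 3 lower of 4429, camera p = 0.00565, or p = 0.237). Without 0 h this wider set passed in both with an estimated correlation too (camera p = 0.00853 and p = 9.38e-05).

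Genes at least 2-fold enriched in Ythdf2 RIP were followed in the same way. Of 2981, 816 had lower and 384 higher slopes in the libraries labelled siIgf2bp3 (median -0.14 against 0 for other genes, camera p = 0.000354, or p = 0.429 with an estimated correlation). Their median was 0.12 over 1 and 2 h (camera p = 1.72e-06, or p = 0.00209 with an estimated correlation). In siVirma the set did not pass (95 higher and 85 lower of 2984, camera p = 0.181 at a fixed correlation), but it pointed up without 0 h (camera p = 2.07e-07, or p = 0.0538 with an estimated correlation) and over 1 and 2 h, with 352 higher and 39 lower (camera p = 3.13e-08, or p = 0.000851). In diffTBLC it pointed up (158 higher and 160 lower of 3033, camera p = 0.0427, or p = 0.33 with an estimated correlation), but did not pass without 0 h (camera p = 0.337 at a fixed correlation). In TBLC_PlaB- it did not pass (camera p = 0.176 at a fixed correlation), but pointed down without 0 h, with 167 higher and 336 lower (camera p = 0.00128, or p = 0.000745 with an estimated correlation), and over 1 and 2 h (camera p = 0.00191, or p = 0.000107).

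The genes 4-fold apart between PrE-T and EPI-T did not pass in the slopes of diffTBLC, siVirma or siIgf2bp3 over all hours (camera p = 0.279 to 0.886 at a fixed and p = 0.314 to 0.85 with an estimated correlation). The PrE-T-high set was lower in diffTBLC over 1 and 2 h, with 27 higher and 68 lower of 1257 (median -0.05 against 0.05, camera p = 0.00025, or p = 0.000875 with an estimated correlation). In siVirma it pointed down without 0 h (camera p = 0.0911, or p = 0.00231 with an estimated correlation), and the EPI-T-high set up (camera p = 0.0455, or p = 0.0331). Over 1 and 2 h the EPI-T-high set pointed up with an estimated correlation in siVirma (camera p = 0.0112) and in siIgf2bp3 (camera p = 0.0392), and passed in neither at a fixed one.

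The m6A peak lists held 11117 and 10496 peaks in TBLC_Ctrl, 10143 and 10443 in TBLC_PlaB- and 12297 and 10478 in diffTBLC. Peaks found in both replicates of a state numbered 8107, 7778 and 8670. After 3 days in SLM 53.7% of diffTBLC consensus peaks overlapped one of TBLC_Ctrl and 3443 (39.7%) lay in no TBLC_Ctrl list. Conversely, 2927 TBLC_Ctrl peaks (36.1%) lay in no diffTBLC list. With inputs not analysed, gained or lost peaks cannot be told from changed expression. After 8 h the change was smaller, with 79.6% of TBLC_PlaB- peaks shared with TBLC_Ctrl and 992 (12.8%) in no TBLC_Ctrl list, and 75.9% of TBLC_Ctrl peaks shared with TBLC_PlaB- and 1399 (17.3%) in no TBLC_PlaB- list. The mean Jaccard overlap was 0.58, 0.583 and 0.589 between replicates, 0.545 between TBLC_Ctrl and TBLC_PlaB-, and 0.314 and 0.325 between diffTBLC and these. Replicates exceeded other pairs by 0.19, the largest of 15 partitions (next 0.159, exact p = 0.0667, the smallest possible). Peaks on chromosome Y numbered 121 and 80 in diffTBLC against 14 to 17 elsewhere.

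**Figure D5:**
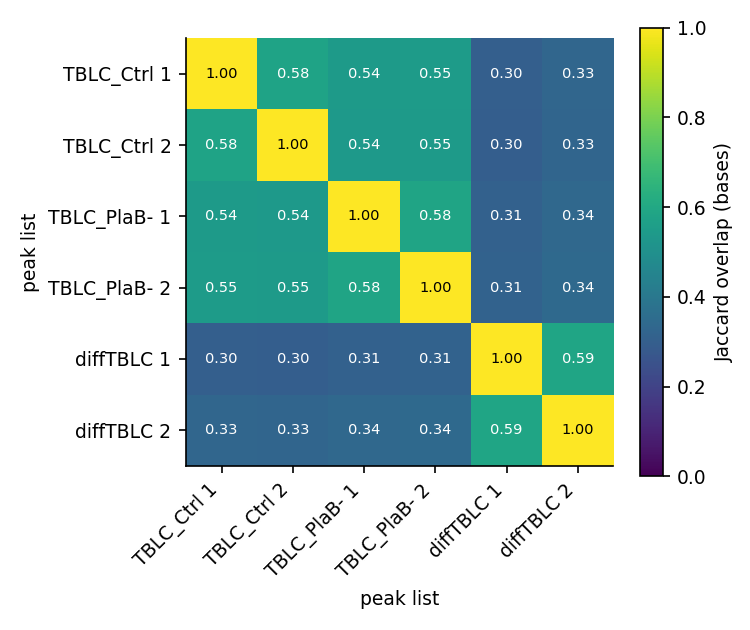
Jaccard overlap, in covered bases on the same strand, between the m6A peak lists of the 3 states and their replicates.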

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

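All tests of explanations in this part were chosen after the results were seen.

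In the actinomycin D tables the difference between the arms was tested for a change with time, and many genes differed from their 0 h value. Between siVirma and siNC1 8129 genes did so at 1 h, 6749 at 2 h and 8019 at 3 h, and between siIgf2bp3 and siNC2 9152, 7915 and 10019. The counts were 3170, 2580 and 4023 between diffTBLC and TBLC, and 2504, 81 and 982 between TBLC_PlaB- and TBLC_Ctrl. The siRNA targets were part of this. The Virma difference shifted by -0.72, -0.62 and -0.96 at 1, 2 and 3 h against 0 h in siVirma, and the Igf2bp3 difference by -1.17, -0.83 and -1.42 in the libraries labelled siIgf2bp3.

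The control siRNA libraries at 0 h stood apart from those at 1 h: the ribosomal protein list dropped by 1.04 in siNC1 and 1.23 in siNC2 and rose again by 0.69 and 0.74 to 2 h. A response of the cells to actinomycin D as the source of this fall is argued against by the 6 other arms, in none of which the list fell from 0 to 1 h (the lowest change was 0.03). Across genes, though, the 0 to 1 h change of diffTBLC correlated with those of siNC1 and siNC2 at 0.50 and 0.47. Against this, TBLC_Ctrl did so at -0.52 and -0.57, siVirma and siIgf2bp3 at -0.25 to -0.36, and TBLC and TBLC_PlaB- at -0.01 to -0.12. With diffTBLC alone in its favour, a part of such a response in the wider change stays open. Libraries of a later time point in place of 0 h are argued against by the short-lived transcripts, which fell from 0 to 1 h in every pair of control libraries (the smallest fall was -0.43). A library or handling batch of the 4 control libraries at 0 h stays open, since the 0 to 1 h changes of siNC1 and siNC2 correlated at 0.98 across genes and the labels name no batch, so it cannot be told apart from a real state of the control cells. Either way it enters the 0 h effects of siVirma and of siIgf2bp3.

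Changes along the same genes were not limited to the first hour. Across genes, those of siNC1 and siNC2 from 2 to 3 h correlated with their own 0 to 1 h changes at 0.67 and 0.78, those of siIgf2bp3 with the same changes at -0.75 and -0.77, and those of diffTBLC at -0.68 and -0.72. The ribosomal protein list rose by 0.74 in siIgf2bp3 over that hour. The 3 h libraries enter the slopes and the averages over 1 to 3 h.

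Fibroblast and feeder genes were higher in PrE-T than in EPI-T, which raised the question of whether fibroblasts are the source of the PrE genes. The list summed to 82 CPM in EPI-T, 287 in PrE-T and 1470 in undifferentiated TBLC, a ratio of 0.195 for PrE-T against TBLC, while the PrE list went up. This argues against fibroblasts as the source of PrE transcripts in PrE-T. Where the fibroblast transcripts themselves come from stays open, because feeder cells are not mentioned in the labels and PrE cells also express collagens.

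The Ythdf2 input held few PrE transcripts although its label gives the same 3 days in SLM as the Igf2bp3 input. Undifferentiated TBLC in its place are argued against by a score of genes differing between diffTBLC and TBLC. The input scored 1.06, TBLC libraries -1.92 to -0.65, EPI-T 0.78, steady-state siRNA 1.06 to 1.34 and diffTBLC at 0 h at least 2.71. A lower share of PrE-T-type cells in that culture stays open, with the PrE list at -3.20 on the log2 scale against the other input, since no library of the same culture shows its share in another way and a batch of this table gives the same value.

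TBLC2 is set here beside TBLC_Ctrl at 0 h and the TBLC of the sorted states, from separately normalized tables. Its mean CPM were 666 for Col1a1 (395 and 336 in the others), 80 for Gata6 (6.5 and 26.4) and 98.2 for Pdgfra (15.8 and 101). Nanog stood at 246 (317 and 108) and Pou5f1 at 734 (1140 and 442).

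For the slopes, 100 of 648 assignments of the libraries to arms within each hour, the real one included, were tried per table. An hour at which the arms are exchanged carries their difference in level into the slope, and more genes differed in level at 0 h than in slope in each table: 11927 against 1188 between diffTBLC and TBLC, 177 against 58 for TBLC_PlaB-, 8242 against 1221 for siVirma and 8928 against 7110 for siIgf2bp3. The assignments therefore do not show what unchanged slopes would give, and whether chance is excluded stays open for all. At least the real number of genes was given by 5, 1, 3 and 4 of the 100 assignments in that order, with 11397, 23, 3770 and 8407 as the highest other counts. For the Igf2bp3 RIP set in siIgf2bp3, 30 with the real one gave a p as small as its own, and the smallest other was 1.05e-13.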

How the results depend on the processing

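Averages over 1 to 3 h, the difference at 1 h and slopes over 1 and 2 h alone were unplanned, the other alternatives planned. The counts of PrE-T against EPI-T, PrE-T and EPI-T against TBLC, both RIPs, diffTBLC against TBLC at 0 h and siVirma and siIgf2bp3 at 0 h stayed within 1.5 times their value under every alternative run. For the counts that did not, and for values that reversed, the cause was not tested. DESeq2 counted 48 genes for siMettl3, 279 for siVirma and 73 for TBLC_PlaB- at 0 h, where the 4 libraries alone gave 94 and the average over 1 to 3 h 2918, and 203 slopes for TBLC_PlaB- and 3172 for siVirma. Its count of calls shared by siVirma at steady state and at 0 h was 224. Library totals left 27 slopes for TBLC_PlaB- and 1 for siVirma (4953 at an unadjusted p under 0.05), and no filter 110 and 6. Scaling to ribosomal protein genes gave 154 slopes for diffTBLC, 12 for TBLC_PlaB-, 0 for siVirma (5246 unadjusted) and 11112 for siIgf2bp3. Leaving out 0 h gave 4728, 3128, 0 (497 unadjusted) and 0 (3231 unadjusted) in the same order. 3 h against 0 h gave 4023, 982 and 8019 for the first 3, and 1 and 2 h alone 2070 for siVirma and 3370 for siIgf2bp3. Of 329 list tests 96 passed with the preset and 27 with an estimated correlation. The Igf2bp3 RIP set in siIgf2bp3 had p = 0.316 with an estimated correlation and turned up over 1 and 2 h alone (p = 1.95e-11). In siVirma, at a fixed correlation, the test pointed up without 0 h (p = 0.264) and over 1 and 2 h alone (p = 1.55e-09). Over 1 and 2 h alone the Ythdf2 RIP set in siIgf2bp3 turned up (p = 1.72e-06 at a fixed correlation). In siVirma that set, which pointed down, turned up without 0 h (p = 2.07e-07) and over 1 and 2 h alone (p = 3.13e-08), and the PrE-T-high set in diffTBLC turned down over 1 and 2 h alone (p = 0.00025 at a fixed correlation). Sets other than that of Igf2bp3 RIP in siIgf2bp3 were unplanned.

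Replicate numbers did not pair the samples (correlations of replicate differences between groups of -0.05 to 0.09). With the replicate number as a block the counts were 9760, 9550 and 9243 for the sorted states, 109 for siMettl3, 884 for siVirma, 8941 and 9838 for Igf2bp3 and Ythdf2 RIP, 11937, 219, 8367 and 9035 for diffTBLC, TBLC_PlaB-, siVirma and siIgf2bp3 at 0 h, and 1024, 40, 406 and 6810 for their slopes. With the block the PrE-T-high set in the TBLC_PlaB- slopes had p = 0.0576 with an estimated correlation, against 0.0467 without it.

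Leaving out 1 library at a time, with a lone library assumed to vary like the other groups, gave 9013 to 9700, 8495 to 9819 and 8189 to 9507 genes for PrE-T against EPI-T, PrE-T against TBLC and EPI-T against TBLC, 8014 to 8327 and 8716 to 9212 for the Igf2bp3 and Ythdf2 RIPs, 11397 to 12051, 7216 to 8313 and 7806 to 8955 for diffTBLC, siVirma and siIgf2bp3 at 0 h and 5340 to 8193 for siIgf2bp3 slopes. For siMettl3 it gave 41 to 148: 41 and 49 without its replicates 1 and 2, and 48 and 49 without those of siNC. For siVirma it gave 495 to 838: 505 and 495 without siNC replicates 1 and 2 and 514 without siVirma replicate 1. TBLC_PlaB- at 0 h ran from 70 to 207: 70 without TBLC_Ctrl replicate 2, and 117 and 73 without its own. Slopes of diffTBLC ran from 630 to 1555: 779 without TBLC 0 h replicate 2, and 669 and 630 without TBLC 3 h. Those of TBLC_PlaB- ran from 8 to 179: 179 and 104 without TBLC_Ctrl 0 h, 16 and 8 without TBLC_Ctrl 3 h, 14 and 11 without TBLC_PlaB- 3 h and 36 without its 2 h replicate 2. Those of siVirma ran from 0 to 5126 and moved in 14 of 16 fits. They were 5126 and 4976 without siNC1 1 h, 239 without siVirma 1 h replicate 1, 1 without siNC1 3 h replicate 1 and 0 in the other 10.

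Of 2153 values of named genes under the alternatives, 1989 kept direction and call, 100 lost the call, 17 gained it and 47 reversed. Pou5f1 in PrE-T against TBLC was -0.29 under library totals and Egr1 in the diffTBLC slopes -0.11 without 0 h. Averaged over 1 to 3 h and at 1 h, values of siVirma against siNC1 were -0.77 and -0.80 for Igf2bp3, -1.36 and -1.55 for Itga6 and -0.86 and -0.92 for Tdg, and Dppa5a was 0.08 at 1 h. In siIgf2bp3 against siNC2 they were -0.58 and -0.61 for Igf2bp3, -0.51 and -0.52 for Virma, 0.56 and 0.29 for Amn, -0.75 and -0.85 for Cubn, -1.29 and -0.74 for Idi1, -1.93 and -1.34 for Itga6, -0.87 and -0.80 for Lamc1, -0.84 and -0.89 for Pdgfra, 0.45 and 0.40 for Pou5f1 and 1.04 and 0.71 for Rplp1. Over 1 and 2 h alone, slope differences in siVirma were 0.16 for Col4a1, 0.14 for Col4a2, 0.02 for Dab2, 0.07 for Nid2 and 0.11 for Virma, and in siIgf2bp3 -0.28 for Amn, 0.17 for Idi1, 0.30 for Igf2bp3, 0.59 for Itga6, 0.13 for Nid2, 0.31 for Pdgfra, -0.28 for Pou5f1, -0.36 for Rplp2, -0.10 for Sox17, 0.31 for Virma and 0.18 for Dab2. Scaled to ribosomal protein genes, Pou5f1 and Sox17 were -0.27 and -0.34 there.

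Tests of m6A-marked genes and their alternatives were not run, for want of an mm39 annotation. On simulated changes of 0.5, edgeR recovered 63% to 64% in the steady-state siRNA table (DESeq2 45% in siVirma) and 64% to 72% in the deeper sorted states, so depth and the spread between replicates as limits were not separated. For genes without a count in a group, depth allows only a lower bound of the fold.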

Other observations

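The lists in this part were planned. The mixture, the PrE-T-high set, averages over 1 to 3 h, distances and correlations were chosen after results were seen.

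PrE-T also differed from EPI-T in genes shared with the trophectoderm, the other extraembryonic lineage. The keratin genes Krt8 (374 ± 18 against 16.9 ± 3.3 CPM, log2 4.46 ± 0.094, n = 2) and Krt18 (3.04 ± 0.14) and the receptor gene Fgfr2 (4.38 ± 0.21), through which FGF4 acts, were higher, and 10 of 15 list members were higher and 3 lower (4 when adjusted over the list alone), although the list did not pass as a whole (adjusted p = 0.068). Krt8 was also higher in PrE-T than in TBLC (2.01 ± 0.079) and lower in EPI-T than in TBLC (-2.45 ± 0.093). The stress factor gene Atf3 was at 31.6 against 0.712 CPM in PrE-T and EPI-T, and the death gene Pmaip1 at 55.9 against 240.

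Of 13 measured DNA methylation and imprint regulators 6 were higher and 7 lower in PrE-T than in EPI-T, and the list did not pass (adjusted p = 0.254). Dnmt3l, the cofactor of de novo methylation, rose from 63.7 CPM in TBLC to 217 in EPI-T and 355 in PrE-T, and Dnmt3b from 89.1 to 325 and 865. Tet1 went from 446 CPM in TBLC to 1060 in EPI-T and 140 in PrE-T, and Zfp57 from 640 to 143 in PrE-T. In diffTBLC against TBLC at 0 h, FGF and ERK response genes split 10 higher and 6 lower of 16 and did not pass as a list (adjusted p = 0.268). Spry4 stood at 223 against 17.9 CPM, Myc at 106 against 13.7 and the BMP target gene Id1 at 272 against 18.8. Over 1 to 3 h of actinomycin D, 16 of 22 measured 2-cell genes were lower and none higher in siVirma than in siNC1 (median -0.75; adjusted p = 0.0214 with an estimated correlation). In siVirma at 0 h 4 were higher and 9 lower of 22 (adjusted p = 0.479). At steady state Zscan4d (0.59 ± 0.14) was higher and none lower of 17 (median 0.20; adjusted p = 0.066).

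The lower PrE-T-high genes in siVirma could reflect fewer PrE-type cells, less PrE transcript per cell, or both. A mixture of the PrE-T and EPI-T profiles in which 1 share changed (0.20 in siNC, 0.13 in siVirma) left a mean squared residual of 5.55 over 428 genes, against 21.06 without the change. Both shares were fitted to these same genes, so the smaller residual does not show that a share changed, and a residual above 1 leaves room for more. The question stays open. Faster decline of these transcripts was tested with the slopes: the set did not shift (camera p = 0.513, or p = 0.314 with an estimated correlation), and without the 0 h libraries it pointed down (p = 0.0911, or p = 0.00231 with an estimated correlation), so this too stays open.

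Distances between libraries of the siVirma and siIgf2bp3 courses are given in chi-square per gene. At 0 h siNC1 and siNC2 libraries lay 2.82 to 4.72 apart, while the replicates of siNC1 lay 3.35 and those of siNC2 1.26 apart. At 2 h siNC1 and siIgf2bp3 libraries lay 2.94 to 5.02 apart, with 3.11 between the replicates of siNC1 and 6.23 to 10.6 between siNC1 and siNC2. At 3 h siNC2 and siIgf2bp3 libraries lay 178 to 202 apart. The replicates of all groups lay 1.11 to 11.06 apart. Averaged over 1 to 3 h, the effects in the siVirma and siIgf2bp3 tables correlated at 0.57, and Virma was lower in the libraries labelled siIgf2bp3 (-0.51 ± 0.036) as Igf2bp3 was in siVirma (-0.77 ± 0.046), whereas the steady-state siVirma effects and those of siIgf2bp3 over 1 to 3 h correlated at 0.00.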
